A study of Mus musculus with 16 samples.

How the data were processed

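RNA from samples labelled brain and liver of 8 male mice, aged 17 weeks, was hybridized to single-colour Illumina bead arrays, 16 arrays in all. The labels give the strain as C57BL/6J, the allele as Pts-R15C-ki, and the genotype of each animal as wild type or homozygous. There were 4 groups of 4 arrays: wild-type brain, homozygous brain, wild-type liver and homozygous liver. The animal identifiers showed that the brain and liver arrays with the same genotype and number came from 1 mouse, and that wild-type and homozygous mice with the same number were different animals.

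The deposited signals were bead summary values with the unit intensity on a linear scale, not normalized between arrays. Beside each signal the deposited table held a detection p-value, which is small where a probe's signal lies above the negative control beads. A second table deposited by the authors held intensity values normalized across all 16 arrays, with array medians between 140.19 and 140.27, and within each array its values had the same rank order as the unnormalized signals. The submitters' processing notes named GenomeStudio 2011.1 without its settings, and the labels named no statistical test.

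Of 25697 probes, 23978 carried 1 gene symbol, 1719 carried none and 0 carried several. The symbols of 23963 probes matched a RefSeq gene table of the mouse assembly GRCm38.p6. That table was used for current symbols and for which genes lie near each other; no coordinates are given, because the deposited tables name no genome build. Probes without a symbol were tested and counted, but not named.

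Signals were background-corrected with the nec function of limma 3.58.1 in R 4.3.3, which uses the detection p-values and an offset of 16, then quantile-normalized within each tissue and put on the log2 scale. A probe was tested in a tissue where its detection p-value was under 0.05 on at least 4 of the 8 arrays. This left 13862 probes of 9562 genes in brain and 11955 probes of 8304 genes in liver. Homozygous and wild-type arrays were compared in each tissue with limma (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Changes are given as log2 of homozygous over wild-type, with the standard error (SE) of the fit and n = 4 arrays per genotype. A probe detected on none of the 4 arrays of a group was called not well above background there. Where it passed the threshold, its change is given as "at least" a fold, computed with the lowest detected signal of each of those arrays as the floor. For probes that did not pass, only the fitted log2 change is given, without a bound, whether or not both groups were detected. On arrays, precision is limited by the number of animals.

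The difference between the genotype effects in liver and brain was tested with limma over the 10492 probes tested in both tissues. An alternative fit took mouse as a block, through the difference between liver and brain in each animal. Enrichment of changed probes near Pts was tested with a two-sided Fisher's exact test on probes of genes within 10 Mb on each side of Pts against all other probes with a chromosome. Single Pts and Nnt probes also had a two-sided exact permutation test.

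The choices in this paragraph were made before the data were examined. There were 45 gene lists, 27 of named genes and 18 of cell type markers, of which 28 applied to brain and 32 to liver. The lists of named genes for both tissues were tetrahydrobiopterin synthesis and recycling, tetrahydrobiopterin-dependent enzymes, genes beside Pts on chromosome 9, circadian clock, glucocorticoid-responsive genes, endoplasmic reticulum stress and integrated stress response, heat shock, oxidative stress response, interferon response and oxidative phosphorylation. Brain lists were immediate early genes, monoaminergic neurons, striatal medium spiny neurons and dopamine receptors, hypothalamic neuropeptides and energy balance, and synaptic transmission. Liver lists were fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, fatty acid oxidation with ketogenesis and PPARA targets, lipid storage and lipoproteins, glucose metabolism, breakdown of phenylalanine, tyrosine and tryptophan, bile acid synthesis and transport, xenobiotic metabolism, male-biased genes, female-biased genes, acute phase and cell proliferation. Cell type markers covered neurons, oligodendrocytes, astrocytes, microglia, endothelium, choroid plexus, pituitary, cerebellum, olfactory bulb, blood, hepatocytes, lymphocytes, neutrophils and monocytes, liver macrophages, stellate cells, bile duct cells, pancreas and adipose tissue. Each list was tested with limma's camera (preset correlation 0.01) on 1 probe per gene, the one with the highest mean signal, and a list with under 4 tested genes was described without a test. Camera with an estimated correlation and fry were run beside it. A preset correlation lets a list pass on few arrays, so the results with an estimated correlation stand beside each call.

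Named genes followed a fixed rule. It took every probe of Pts and of Nnt, which marks C57BL/6 substrains, and in each tissue the 12 largest rises and 12 largest falls among probes past the threshold, with 1 probe per gene. Where fewer than 24 passed, it took those with the smallest p up to 12 in all. It took up to 4 members past the threshold from each list, or 2 with the smallest p where none passed, and up to 6 genes each way for the difference between tissues. Genes named outside the rule are marked in the text as chosen after their values were seen.

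Alternatives covered background correction, median centring, normalization over all arrays, the authors' normalized values, the detection filter, array weights, the variance model, the threshold, a block for replicate number, a shared fit of both tissues, and the window around Pts. They also covered the probe used per gene and leaving out each array in turn. Chosen after seeing the data were fits without wild-type mice 1 and 2, array brightness (the 75th percentile of deposited signal) as a covariate or a block, the lists without genes within 20 Mb of Pts, and limma on each list's mean per array. The replicate number was checked for pairing. Within brain, the deviations of wild-type and homozygous arrays with the same number correlated across genes (which are not independent replicates) at 0.56, -0.46, -0.51 and 0.42, and 1 of 4 wild-type arrays was closest to its own number; in liver 0 of 4 were. No pairing between genotypes was therefore used.

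The fits were tested on simulated data with 200 changed probes. In brain, the fit recovered 23.9% of changes of log2 0.5, 83.6% of changes of 1 and 98.5% of changes of 2. In liver it recovered 29.9%, 79.1% and 98.5%, and for the difference between tissues 8.96%, 56.7% and 93.9%. The simulated noise was independent between probes, without the brightness that brain arrays shared. With fewer than 200 changed probes the adjusted threshold is also stricter. These shares therefore need not hold for the real comparisons. The robust variance alternative used statmod 1.5.0. Slide positions were not used here.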

Results

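Brain and liver transcripts were measured in 4 wild-type and 4 homozygous male mice carrying the Pts-R15C-ki allele, a knock-in of the change R15C in Pts. Pts encodes pyruvoyl-tetrahydropterin synthase, the second enzyme in the synthesis of tetrahydrobiopterin, which is the cofactor of the aromatic amino acid hydroxylases, of nitric oxide synthases and of alkylglycerol monooxygenase. The title of the series concerns a mild defect of tetrahydrobiopterin synthesis and the distribution of body fat, and the arrays compare genotypes in both tissues. Between 13241 and 14576 probes were detected on the 8 brain arrays and between 11785 and 12315 on the 8 liver arrays. The mean number detected was 13939 ± 563 (SD, n = 4) in wild-type brain and 13698 ± 470 in homozygous brain, 12002 ± 159 in wild-type liver and 11968 ± 242 in homozygous liver.

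Brain arrays differed in brightness. Wild-type mice 1 and 3 and homozygous mice 1 and 2 had a 75th percentile of signal between 302.04 and 343.32, and the other 4 brain arrays had one between 240.62 and 270.93, with 2 arrays of each genotype in each set. The first principal component of brain, with 51.7% of the variance, separated these sets. In liver the first component held 62.2% of the variance, and wild-type mice 1 and 2 lay at -43.8 and -46.4 on it, while the other 6 liver arrays lay between 2.79 and 20.9.

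The targeted gene itself was measured with 2 probes. In liver, Pts signal was higher in homozygous mice by 0.58 (SE 0.12, adjusted p = 0.054 by limma) on the brighter probe and by 0.90 (SE 0.20, adjusted p = 0.0624) on the other, and neither passed the threshold. All 4 homozygous livers lay above all 4 wild-type livers on both probes (exact permutation p = 0.0286, n = 4, the smallest the design allows). The groups also did not overlap for 13.0% of all tested liver probes, so this separation was not particular to Pts. In brain the brighter probe was higher by 0.39 (SE 0.15) and the other by 0.69 (SE 0.19), both with an adjusted p of 1 in limma, and the exact permutation p was 0.0857 and 0.0286 (n = 4). With brightness as a block, the dimmer probe passed in brain at 0.69 (SE 0.07, adjusted p = 0.0192), an alternative chosen after seeing the data. The brighter probe passed in liver with no background subtraction (adjusted p = 0.0453), with the authors' values (0.0409), with trend and robust variance (0.0428), with array weights (0.00718), with all arrays in 1 fit (0.0212), without wild-type mouse 3 (0.0307) and without wild-type mouse 4 (0.0459). The 3 probes of Nnt, nicotinamide nucleotide transhydrogenase, were detected on 0 of 16 arrays.

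**Figure D1:**
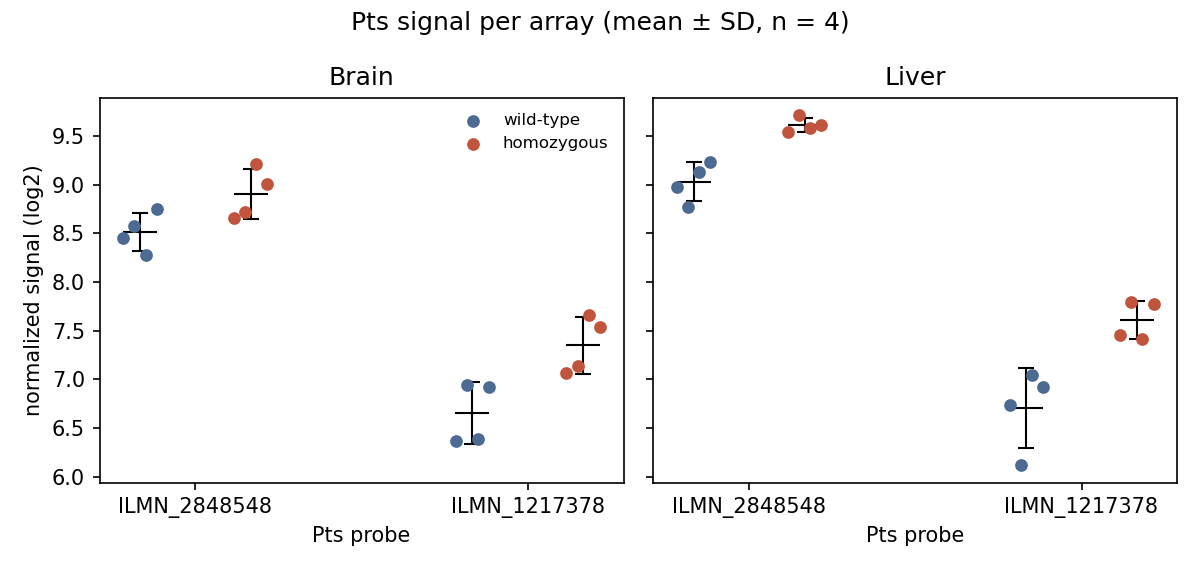
Normalized log2 signal of both Pts probes on each array, wild-type in blue and homozygous in red, with the mean and SD (n = 4); the points of each group are spread sideways for legibility. Homozygous means exceeded wild-type means by 0.39 and 0.69 in brain and by 0.58 and 0.90 in liver.

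In brain, the comparison asked which transcripts differ where tetrahydrobiopterin serves the synthesis of monoamine transmitters. Tmem25, a transmembrane protein of the immunoglobulin superfamily, fell by 6.78 (SE 0.15, adjusted p = 6.93e-09, limma) and was not well above background on any of the 4 homozygous arrays, so the change was at least 77.0-fold lower. Alg9, a mannosyltransferase of N-glycan assembly, fell by 1.32 (SE 0.12, adjusted p = 0.00407), at least 2.06-fold lower, and was detected on 4 wild-type and 0 homozygous arrays. The changes rested on 1 probe of each gene: the other probes read -0.39 and -0.18 for Tmem25, and -0.27 and -0.19 for Alg9, with adjusted p of 1. Of 13862 probes, 0 rose and 2 fell, while 439 (3.17%) had an unadjusted p under 0.05 by limma. The groups did not overlap for 286 probes (2.06%), where chance gives 2.86%.

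The probes next in rank did not pass in brain. Cryab, a small heat shock protein, was at -0.99 (SE 0.13, adjusted p = 0.0645). Edn1, the precursor of endothelin, was at -0.80 (SE 0.14, adjusted p = 0.550). An adjusted p of 0.913 belonged to Srpr at -1.50, Mkks at -1.18, H2ax at -0.73, Phka1 at -0.56, Fxyd2 at 0.75, Arcn1 at 0.64, Defb11 at 0.54 and Evi2 at 0.51. Of these genes next in rank, at least Cryab, Srpr and H2ax lay within 20 Mb of Pts.

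Of the 10 genes of tetrahydrobiopterin synthesis and recycling, 7 were tested in brain and 0 passed, with a median of 0.05 (camera adjusted p = 0.253) and Qdpr, the recycling dihydropteridine reductase, at 0.22 (SE 0.11). The 4 tested tetrahydrobiopterin-dependent enzymes had a median of 0.01 (0.937), with the serotonin-synthesizing hydroxylase Tph2 at 0.08 (SE 0.14) and the neuronal nitric oxide synthase Nos1 at -0.05 (SE 0.14). Markers of monoaminergic neurons had a median of -0.002, a mean of 0.02 and an upward test (11 tested, 0.923), with En1 at 0.22 and Maob at -0.15. Striatal neurons and dopamine receptors had a median of 0.02 and a mean of 0.001 with a downward test (8 tested, 0.923), with Gpr6 at -0.21 and Tac1 at 0.08. Hypothalamic neuropeptides had a median of 0.04 (12 tested, 0.46), with vasopressin (Avp) at 0.29. Synaptic transmission genes had a median of 0.008, a mean of -0.02 and a downward test (12 tested, 0.923), with Gabrb2 at -0.31.

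Lists past the threshold in brain were 4 of 26 tested, all lower in homozygous mice. Markers of neutrophils and monocytes had a median of -1.21 (4 tested, camera adjusted p = 2.21e-05; adjusted p = 0.513 with an estimated correlation), and adjusted over the list alone 4 fell, with the calprotectin subunits S100a8 at -1.99 (SE 0.74) and S100a9 at -1.70 (SE 0.65). Glucocorticoid-responsive genes had a median of -0.36 (10 tested, 0.00331; adjusted p = 0.513 with an estimated correlation), with Tsc22d3 at -0.45 and the glucocorticoid receptor co-chaperone Fkbp5 at -0.75. Endoplasmic reticulum stress genes had a median of -0.16 (13 tested, 0.0118; adjusted p = 0.513 with an estimated correlation), with Creld2 at -0.46 and Hyou1 at 0.51. Heat shock genes had a median of -0.23 (10 tested, 0.0141; adjusted p = 0.564 with an estimated correlation), with Hspa1a at -0.81 and Hsph1 at -0.43. Adjusted over the list alone, 0 genes of the last 3 lists passed in limma.

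These 4 lists moved with wild-type mice 1 and 2. The mean of the neutrophil and monocyte list was 1.73 and 1.62 on those brain arrays, against -0.61 and -0.20 in wild-type mice 3 and 4 and between -0.80 and -0.33 in the homozygous mice. The glucocorticoid list stood at 0.48 and 0.60 in wild-type mice 1 and 2, at -0.25 and -0.23 in wild-type mice 3 and 4, and between -0.18 and -0.13 in homozygous mice. Heat shock genes stood at 0.25 and 0.46 and endoplasmic reticulum stress genes at 0.18 and 0.24 in wild-type mice 1 and 2, and both lists stood under 0 on the other 6 brain arrays. Without wild-type mice 1 and 2, the medians were -0.21, 0.12, -0.04 and -0.07 in the order given, and 0 of the 4 lists passed (adjusted p = 0.256, 0.292, 0.741 and 0.995). In that fit 1 list passed, olfactory bulb markers, with a median of 0.26 (adjusted p = 0.0206; 0.53 with an estimated correlation and 0.429 by limma on the list mean). Leaving out wild-type mouse 1 alone ended the glucocorticoid, endoplasmic reticulum stress and heat shock calls (0.133 for each), as did leaving out wild-type mouse 2 (0.181, 0.151 and 0.181). The heat shock call also ended without homozygous mouse 1 (0.0909) or homozygous mouse 2 (0.0542). Fry called 0 of 26 lists directionally (smallest adjusted p = 0.387), and limma on the list means called 0 (smallest 0.343).

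Of the other brain lists, genes beside Pts had a median of 0.04, a mean of -0.06 and a downward test (18 tested, camera adjusted p = 0.33). Adjusted over the list alone 1 rose and 3 fell, with Cryab at -0.99 and Bco2 at -0.45. Fry's mixed test, which asks for change in either direction, gave an adjusted p of 0.000953. The clock genes had a median of 0.01 (0.798), with Nr1d2 at 0.21 and Per2 at -0.28. Oxidative stress genes had 0.05 (0.806), with Gstm1 at -0.11. Interferon genes had -0.09 (0.804), with Ifit3 at 0.19. Oxidative phosphorylation genes had 0.005 with a downward test (0.99), with Atp5a1 at 0.19. Immediate early genes had 0.09 (0.253), with Egr2 at 0.40. Cell type markers had medians of 0.06 for neurons (0.46), 0.10 for oligodendrocytes (0.171), and -0.01 for astrocytes (0.864). They were -0.15 for microglia (0.152), -0.12 for endothelium (0.171), -0.02 for choroid plexus (0.692), 0.02 for cerebellum (0.806) and 0.20 for olfactory bulb (0.0636). Blood markers had a median of 0.007, a mean of -0.11 and a downward test (0.692), and lymphocyte markers had a median of -0.06 (0.864). Of hepatocyte markers 3 genes were measured, with a median of 0.02 and Apoa1 at 0.07, and of pituitary markers 0 were, so neither was tested. Examples among these were the myelin gene Opalin at 0.84 (SE 0.33), the complement gene C1qa at -0.48 (SE 0.20) and the microglial receptor P2ry12 at 0.49 (SE 0.16). Others were Gfap at -0.22, Ly6c1 at -0.61, Sp8 at 0.44, Slc4a1 at -0.64, Gad1 at 0.16, Otx2 at -0.18, Gabra6 at 0.14 and Cd3e at 0.16. None of these examples passed in limma (adjusted p = 1).

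The brain count was 0 with the strict detection filter, where limma tested 10608 probes without those of Tmem25 and Alg9. It was 1 with the authors' values, 1 with the replicate number as a block, 4 without homozygous mouse 2, and 5 with brightness as a block. The 5 were Tmem25, Alg9, Cryab at -0.99 (adjusted p = 0.0284), H2ax at -0.73 (0.0327) and the dimmer Pts probe, and all 5 genes lay within 20 Mb of Pts. Within the 4 brighter arrays the count was 4 and within the 4 dimmer arrays 1. The count was 2 without wild-type mice 1 and 2, with Tmem25 among them, while Alg9 read -1.27 (SE 0.16) and did not pass (adjusted p = 0.207).

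Changed probes gathered around Pts on chromosome 9 in both tissues, which matters because a knock-in made in cells of another strain can carry flanking sequence. In liver, 19 of 129 tested probes within 10 Mb of Pts passed (14.7%), of which 4 rose and 15 fell, against 82 of 11137 elsewhere (0.736%; Fisher's exact p = 2.5e-18). In brain, 2 of 156 passed within 10 Mb against 0 of 12905 elsewhere (Fisher's exact p = 0.000142), and at an unadjusted p under 0.01 there were 14 against 57 (Fisher's exact p = 8.93e-14). These tests counted each probe, and some genes had more than 1, so their units were not independent. The 4 that rose in liver were Sorl1, a sorting receptor, at 1.79 (SE 0.32), the apolipoprotein gene Apoa4 at 1.76 (SE 0.32), the sodium pump regulator Fxyd6 at 1.53 (SE 0.16) and the cytokine gene Il18 at 1.19 (SE 0.15). Those that fell included Tmem25 at -5.31 (SE 0.52), the nicotinamide methyltransferase Nnmt at -4.42 (SE 0.70) and -4.01 (SE 0.66) on its 2 probes, Nxpe2 at -1.72 (SE 0.19), and Alg9 at -1.22, -0.90 and -0.60 on its 3 probes. Chosen after their values were seen, H2ax at -1.29, Dnaja4 at -1.14, Pkm at -1.04, Atm at -0.99 and, on a probe detected on 0 homozygous arrays, at least 1.16-fold lower, Mcam at -0.99 and Trappc4 at -0.54 and -0.57 completed the 19 probes.

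Tmem25 in liver again rested on 1 probe, detected on 0 of 4 homozygous arrays and at least 30.5-fold lower, while its other probes read 0.50 and 0.40 (adjusted p = 0.340 and 0.377). Of genes called in liver within 20 Mb of Pts and tested in brain, 12 of 13 had the same sign in brain, against 35 of 53 elsewhere (1 probe per gene, Fisher's exact p = 0.0884, an alternative chosen after seeing the data). Counted by probe it was 15 of 16 against 40 of 61 (Fisher's exact p = 0.0303), with a median size of change in brain of 0.46 against 0.12. The list of genes beside Pts had a median of 0.12 and a mean of -0.09 in liver with an upward test (16 tested, camera adjusted p = 0.674). Il18 rose, and Nnmt and Alg9 fell. Adjusted over the list alone 2 rose and 2 fell, and fry's mixed test, which 19 of 27 liver lists passed, gave an adjusted p of 0.00122. Counts within 5 Mb were 11 in liver and 1 in brain (Fisher's exact p = 1.84e-12 and 0.00947), and without wild-type mice 1 and 2 they were 8 and 1 within 10 Mb (4.26e-11 and 0.0237).

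**Figure D2:**
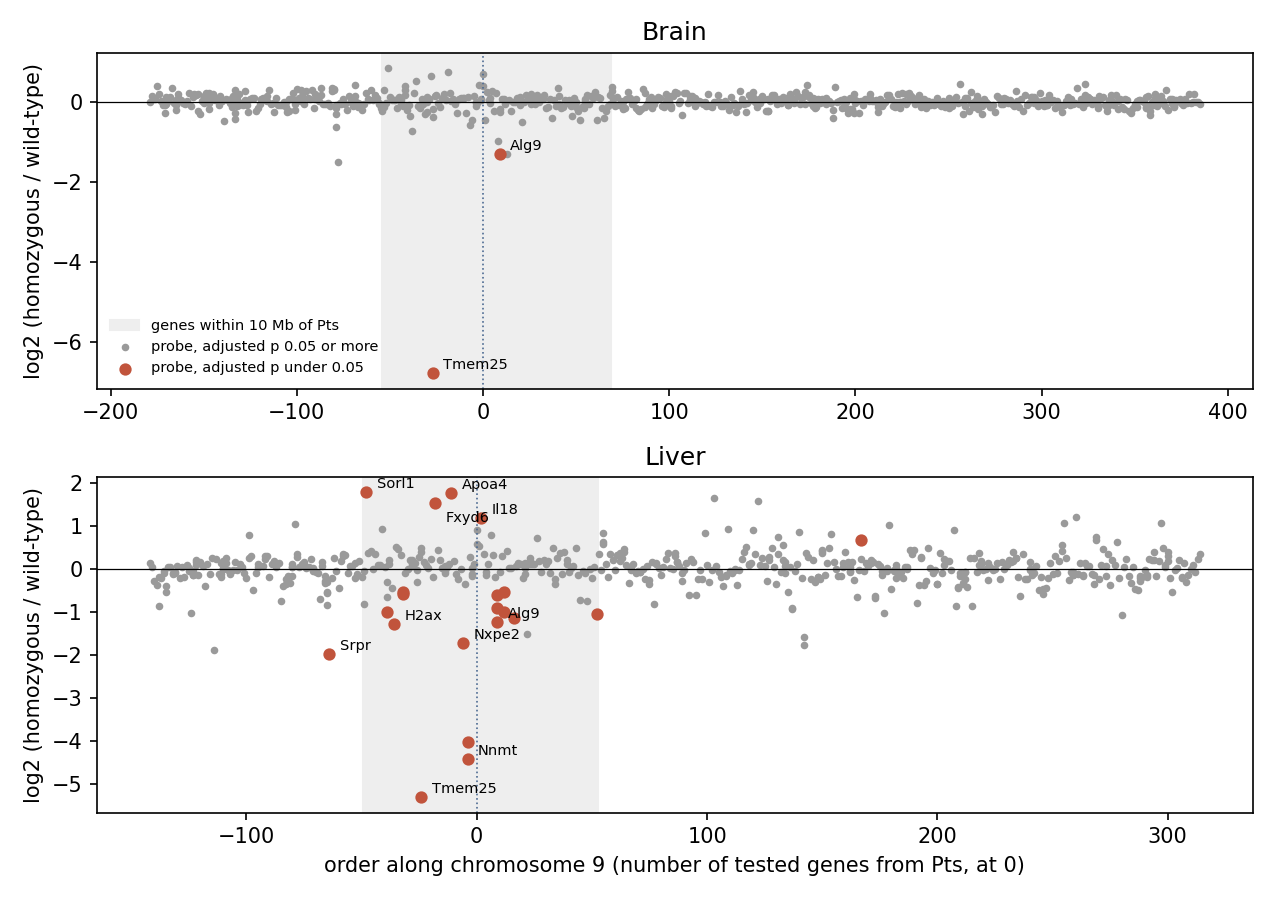
Log2 change of each tested probe on chromosome 9 in brain and liver, by the number of tested genes between its gene and Pts at 0; grey shading marks genes within 10 Mb and red points an adjusted p under 0.05. In liver 19 of the 21 red points lie in the shaded window, and in brain both do.

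In liver, camera with the preset correlation placed 6 lists lower in homozygous mice, among them acute phase genes and macrophage markers, and 7 lists higher. With an estimated correlation 0 lists passed (smallest adjusted p = 0.276), and without wild-type mice 1 and 2 the preset call ended for 1 of the 6 and 4 of the 7. Saa1 and Saa2, serum amyloid A genes of the acute phase response, fell by 4.85 (SE 0.90, adjusted p = 0.0453, limma) and 4.37 (SE 0.73, 0.0442). The hepatokine gene Fgl1 fell by 2.09 (SE 0.22, 0.00843) and S100a8 fell by 2.51 (SE 0.48, 0.0490). Rgs16, a regulator of G protein signalling, rose by 3.36 (SE 0.60, 0.0453), and Mfsd2a, a transporter of lysophosphatidylcholine induced by fasting, rose by 1.40 (SE 0.16, 0.00854). Of the 8 fits that left out 1 array, Saa1 and S100a8 passed in 1, Saa2 and Rgs16 in 2, Mfsd2a in 7 and Fgl1 in 8. In all, 108 of 11955 probes passed, 44 that rose and 64 that fell, for 94 named genes.

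Other large rises were Slc17a8 at 1.73 (SE 0.31), a vesicular glutamate transporter, and 9130409I23Rik at 1.61 (SE 0.14, adjusted p = 0.00576, the smallest in liver). Then came the carboxylesterase Ces1e at 1.25 (SE 0.23), the organic anion transporter Slco1a4 at 1.23 (SE 0.18), Fam13a at 1.17 (SE 0.21) and the autophagy gene Gabarapl1 at 1.10 (SE 0.20). Further falls were the fatty acid binding protein Fabp5 at -2.04 (SE 0.28) and the signal recognition particle receptor Srpr, a gene within 20 Mb of Pts, at -1.98 (SE 0.31). After them came the nuclear envelope protein Syne4 at -1.81 (SE 0.18), the tubulin Tubb2b at -1.74 (SE 0.25) and the dynein light chain Dynll1 at -1.68 (SE 0.31). For each of these genes all 4 homozygous livers lay beyond all 4 wild-type livers. The groups did not overlap for 1549 probes (13.0%, where chance gives 2.86%), and 2701 (22.6%) had an unadjusted p under 0.05.

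**Figure D3:**
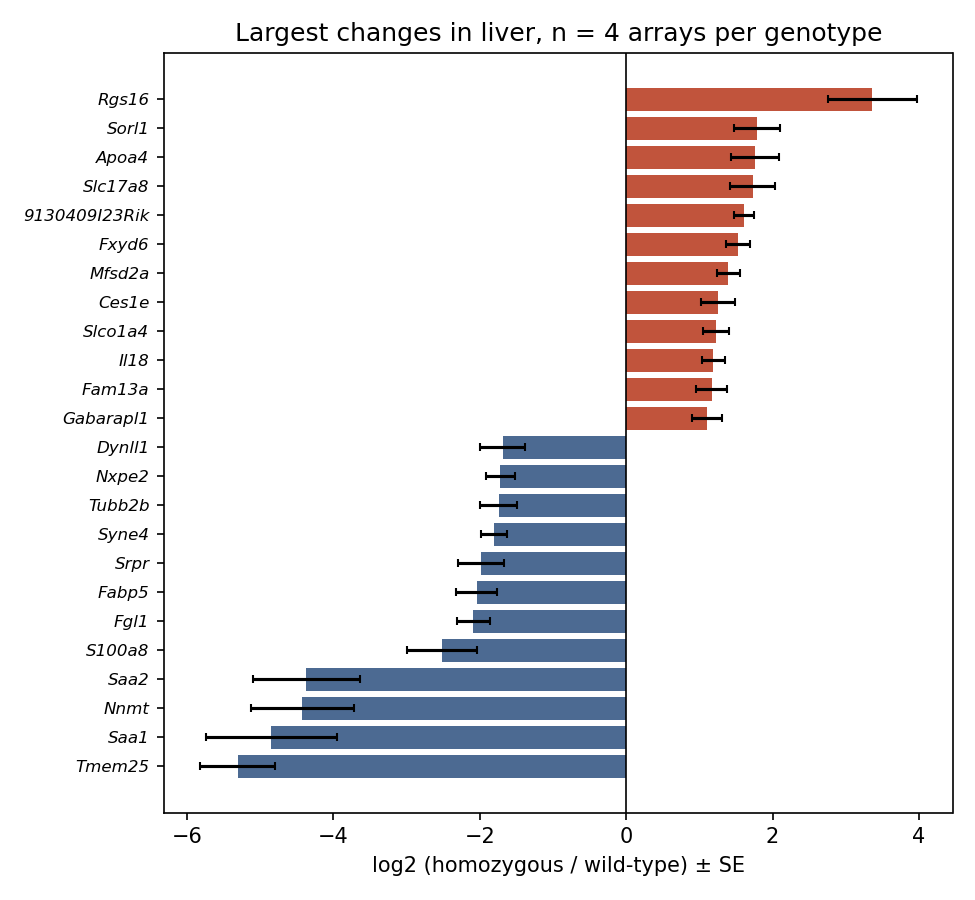
Log2 change with its SE (limma, n = 4 per genotype) for the 12 largest rises (red) and 12 largest falls (blue) in liver, 1 probe per gene. Changes run from 3.36 for Rgs16 to -5.31 for Tmem25.

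The acute phase list was lower in homozygous livers, with 21 of 21 tested genes below 0 and a median of -1.08 (camera adjusted p = 8.36e-10; adjusted p = 0.308 with an estimated correlation). Of these, 3 fell over all probes (Saa1, Saa2 and Orm1, an orosomucoid, at -1.08 with SE 0.20) and 12 fell adjusted over the list alone. Glucocorticoid-responsive genes, a list that as fixed shared Lcn2 with the acute phase list, had a median of -0.94 and a mean of -1.41 (11 tested, 0.00167; adjusted p = 0.283 with an estimated correlation). Ddit4, an inhibitor of mTORC1 signalling, fell by 1.01 (SE 0.18), and 3 fell adjusted over the list alone. Heat shock genes had a median of -0.59 (9 tested, 0.000577; adjusted p = 0.339 with an estimated correlation), with Hsph1 at -1.60 and Chordc1 at -1.03. Of these, 0 passed in limma over all probes and 4 fell adjusted over the list alone. Endoplasmic reticulum stress genes had a median of -0.43 (14 tested, 0.0247; adjusted p = 0.431 with an estimated correlation). The transcription factor Atf4 fell by 1.12 (SE 0.20), its target Trib3 rose by 1.03 (SE 0.18), and adjusted over the list alone 1 rose and 4 fell.

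These stress lists too stood apart in wild-type mice 1 and 2. The mean of the acute phase list was 1.75 and 1.81 in their livers, -0.25 and 0.21 in wild-type mice 3 and 4, and between -1.04 and -0.73 in homozygous mice. Glucocorticoid-responsive genes stood at 1.49 and 1.67, then -0.15 and -0.19, then between -0.83 and -0.59 in the same order. Heat shock genes stood at 0.62 and 0.86, -0.07 and -0.06, and between -0.43 and -0.21. Without wild-type mice 1 and 2 the acute phase median was -0.35 (adjusted p = 5.45e-09), the glucocorticoid median -0.19 (0.0236), the heat shock median -0.12 (0.0236) and the endoplasmic reticulum stress median -0.06 (0.521, not past). With an estimated correlation the first 3 did not pass in that fit (adjusted p = 0.302 for each), and heat shock also missed by limma on the list mean (0.103). The endoplasmic reticulum stress list also missed the threshold without wild-type mouse 1 (adjusted p = 0.0525) or without wild-type mouse 2 (0.0895).

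Macrophage markers were lower in homozygous livers in a different arrangement. Of 8 tested, 8 were below 0, with a median of -0.66 (camera adjusted p = 7.22e-07; adjusted p = 0.276 with an estimated correlation). The complement genes C1qc and C1qb fell by 1.05 (SE 0.19) and 0.99 (SE 0.17), the complement receptor gene Vsig4 fell by 1.04 (SE 0.17), and adjusted over the list alone 6 fell. The list mean was 0.25, 0.39, 0.19 and 0.52 in wild-type mice 1 to 4 and between -0.49 and -0.06 in homozygous mice, and the median without wild-type mice 1 and 2 was -0.77 (1.28e-07; 0.302 with an estimated correlation). Of neutrophil and monocyte markers only 3 were tested and all 3 fell, S100a8 and the lysozyme genes Lyz1 at -1.05 (SE 0.15) and Lyz2 at -0.96 (SE 0.18), also adjusted over the list alone. Bile duct markers had a median of -0.64 (4 tested, 0.00388; adjusted p = 0.276 with an estimated correlation). The keratin Krt8 fell by 0.83 (SE 0.15), and 2 fell adjusted over the list alone. The list mean was 0.54 and 0.56 in wild-type mice 1 and 2, 0.03 and 0.07 in wild-type mice 3 and 4, and between -0.38 and -0.19 in homozygous mice. Without wild-type mice 1 and 2 the bile duct median was -0.35 (0.0236; 0.302 with an estimated correlation).

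**Figure D4:**
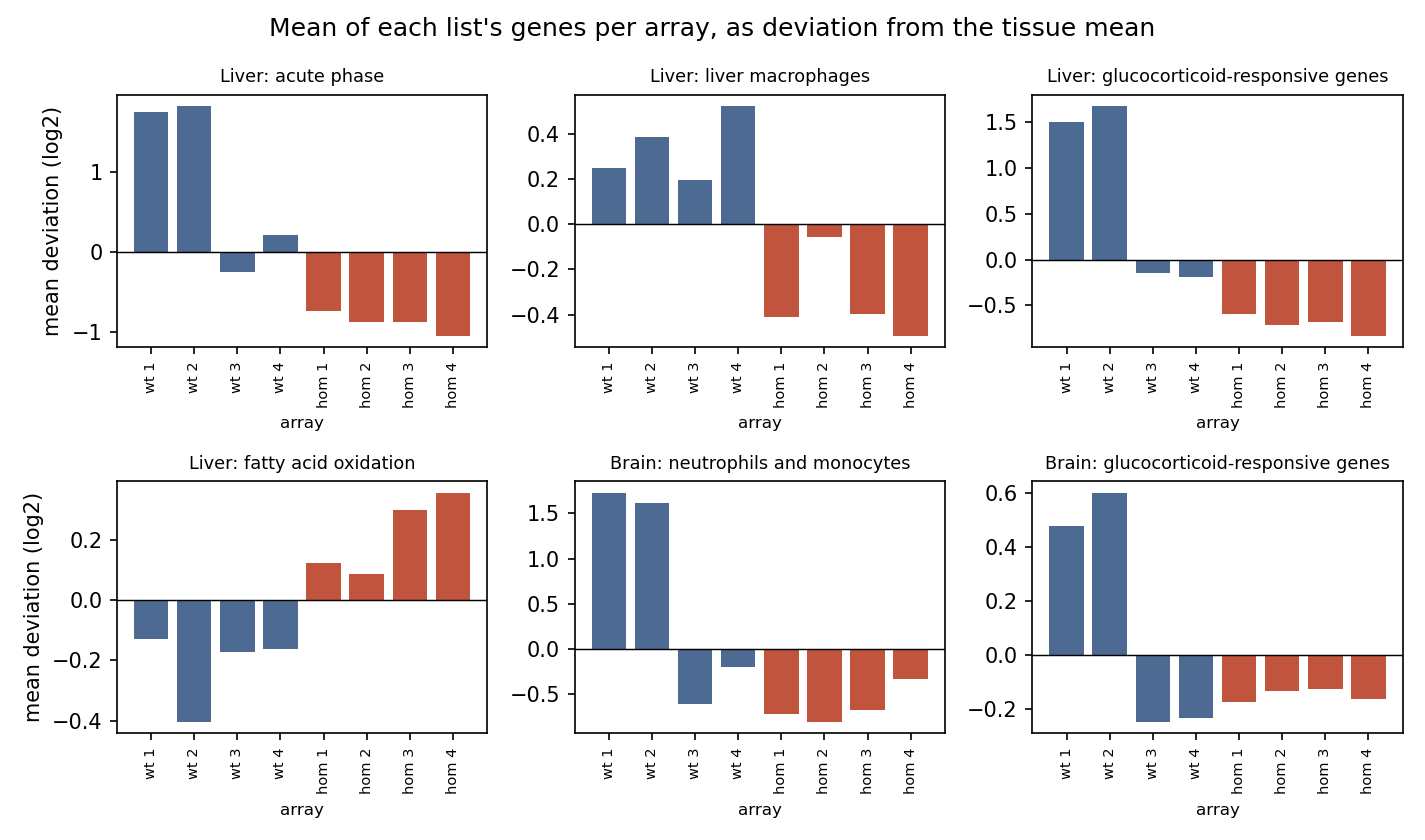
Mean over the genes of 6 lists on each array, as log2 deviation from the mean of the tissue, with wild-type mice (wt) in blue and homozygous mice (hom) in red; bars start at 0 and the vertical scale differs between panels. Wild-type mice 1 and 2 reach 1.75 and 1.81 for the acute phase in liver and 1.73 and 1.62 for neutrophils and monocytes in brain.

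Among metabolic lists, fatty acid oxidation with ketogenesis and PPARA targets was higher in homozygous livers, with a median of 0.30 (17 tested, camera adjusted p = 0.0015; adjusted p = 0.276 with an estimated correlation). The fatty acid hydroxylase Cyp4a14 was at 2.47 (SE 0.51, adjusted p = 0.0558) and the receptor Ppara at 0.55 (SE 0.12, 0.0643). Of the list, 0 passed in limma over all probes and 4 rose adjusted over the list alone. The list mean lay between -0.40 and -0.13 in all 4 wild-type livers and between 0.09 and 0.36 in all 4 homozygous livers. Oxidative phosphorylation had a median of 0.19 (17 tested, 0.00167; adjusted p = 0.308 with an estimated correlation), with Sdhb at 0.66 and Atp5a1 at 0.44, and 2 rose adjusted over the list alone. Bile acid synthesis and transport had a median of 0.26 (13 tested, 0.0189; adjusted p = 0.283 with an estimated correlation), with the sterol hydroxylase Cyp8b1 at 1.06 and the bile acid transporter Slc10a1 at 1.14, and 2 rose adjusted over the list alone. Xenobiotic metabolism had a median of 0.37 (16 tested, 0.0189; adjusted p = 0.339 with an estimated correlation). Cyp3a11 rose by 0.76 (SE 0.10, adjusted p = 0.0251), and 3 rose adjusted over the list alone.

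Glucose metabolism had a median of 0.37 (13 tested, camera adjusted p = 0.0299; adjusted p = 0.276 with an estimated correlation). The liver glycogen synthase Gys2 rose by 0.92 (SE 0.17), and 5 rose and 1 fell adjusted over the list alone. Breakdown of phenylalanine, tyrosine and tryptophan had a median of 0.27 (10 tested, 0.0189; adjusted p = 0.339 with an estimated correlation), with the tryptophan dioxygenase Tdo2 at 0.73 and Afmid at 0.89, and 5 rose adjusted over the list alone. Tetrahydrobiopterin synthesis had a median of 0.28 (8 tested, 0.0339; adjusted p = 0.339 with an estimated correlation), with Pts at 0.58 and the cyclohydrolase regulator Gchfr at 0.40, and 1 rose adjusted over the list alone. Of the tetrahydrobiopterin-dependent enzymes 1 was tested on the list's probe, endothelial nitric oxide synthase Nos3, at -0.60 (SE 0.23), and another probe of Nos3 fell by 0.99 (SE 0.18, adjusted p = 0.0453).

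Wild-type mice 1 and 2 stood lowest on several of these lists. Their means were -0.49 and -0.62 for bile acids, -0.35 and -0.47 for xenobiotic metabolism, -0.38 and -0.22 for glucose metabolism, -0.36 and -0.27 for amino acid breakdown and -0.32 and -0.28 for tetrahydrobiopterin synthesis. Without these mice the lists for fatty acid oxidation (median 0.35, camera adjusted p = 0.000109), oxidative phosphorylation (0.15, 0.00815) and bile acids (0.19, 0.0405) passed. With an estimated correlation they did not (adjusted p = 0.302, 0.386 and 0.386), and by limma on the list means only fatty acid oxidation did (0.0399, against 0.216 for each of the others). Glucose metabolism (0.03, 0.351), amino acid breakdown (0.20, 0.065), xenobiotic metabolism (0.13, 0.081) and tetrahydrobiopterin synthesis (0.07, 0.266) missed the camera threshold without these mice. Single arrays also ended calls. Glucose metabolism missed the threshold without wild-type mouse 1 (0.0581), wild-type mouse 3 (0.0849) or homozygous mouse 2 (0.0524). Tetrahydrobiopterin synthesis missed it without wild-type mouse 1 (0.0799) or homozygous mouse 1 (0.0534) and without genes within 20 Mb of Pts, which removes Pts itself (0.12), and xenobiotic metabolism without wild-type mouse 3 (0.0588).

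Lists that did not pass in liver included lipid storage and lipoproteins with a median of 0.16 (16 tested, camera adjusted p = 0.0626), of which Apoa4 rose. Fatty acid and triglyceride synthesis had 0.20 (0.0879), with the desaturase Fads2 at 0.78, and cholesterol synthesis had -0.18 (0.129), with Sqle at -0.83. Oxidative stress genes had 0.10 (0.318), with Gclc at 0.40. Interferon genes had a median of 0.14, a mean of 0.02 and a downward test (0.674), with Ifi27 at -0.75. Male-biased genes had -0.21 (0.18), with Cyp7b1 at -0.71; cell proliferation had -0.10 (0.132), with Mcm6 at -0.66, whose other 2 probes fell by 0.65 (SE 0.11, adjusted p = 0.0421) and 0.85 (SE 0.16, 0.0453). Markers of endothelium had 0.04 (0.845), with Egfl7 at 0.25, and of blood 0.50 (0.142), with Hba-a1 at 0.73. Markers of hepatocytes had 0.13 (0.0818), with Alb at 0.44, of stellate cells -0.16 (0.245), with the collagen Col1a1 at -1.08, and of lymphocytes 0.26 (0.18), with H2-Aa at 0.46. Besides the tetrahydrobiopterin-dependent enzymes and the neutrophil and monocyte markers, lists with under 4 tested genes were female-biased genes (2 genes, median 0.18, Abcd2 at 0.64), adipose tissue (3 genes, 0.39, Car3 at 0.63) and pancreas (1 gene, Cela2a at -0.16). Of 27 lists tested, camera called 13 with the preset correlation, 7 up and 6 down, and 0 with an estimated correlation (smallest adjusted p = 0.276). Fry called 11 (9 of the 13), and limma on the list means called 5.

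The liver count moved when single arrays were left out: 12 probes without wild-type mouse 1, 19 without mouse 2, 944 without mouse 3, 168 without mouse 4, and 14, 70, 10 and 9 without homozygous mice 1 to 4. Of the 108, 9 passed in all 8 of these fits and all 108 kept their sign. The 9 were probes of 9130409I23Rik, Fxyd6, Syne4, Tmem25, Fgl1, Nxpe2 and Alg9, a probe without a symbol and, chosen after its value was seen, Ifi27l2a. Without wild-type mice 1 and 2, 23 passed (20 of the 108), all 108 had the same sign, and the median size went from 0.99 to 0.82. S100a8 (-1.62), Saa1 (-3.12) and Dynll1 (-1.09) moved by over 1.5 times in that fit. Median centring gave 37 that rose and 132 that fell, 21.9% risen against 40.7%.

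The last comparison asked whether the effect of genotype differed between liver and brain. Of 10492 probes tested in both tissues, 8 passed in limma, 3 with a higher effect in liver and 5 with a lower one, and 1232 had an unadjusted p under 0.05. The lysophosphatidylcholine transporter Mfsd2a differed by 1.78 (SE 0.31, adjusted p = 0.0411), at 1.40 in liver and -0.39 in brain. Fxyd6 differed by 1.50 (SE 0.20, 0.00766), at 1.53 and 0.03. Effects lower in liver were found for Syne4 by -1.67 (SE 0.24, 0.00925), Tubb2b by -1.78 (SE 0.29, 0.0248), Nos3 by -1.29 (SE 0.22, 0.0337), the cytidine triphosphate synthase Ctps by -1.29 (SE 0.23, 0.0413) and the adhesion molecule Mcam by -1.27 (SE 0.22, 0.0411), and the eighth probe carried no symbol. With mouse as a block 3 passed, Mfsd2a, Fxyd6 and Syne4, all of them among the 8. The count was 1 without wild-type mice 1 and 2 and 179 without the liver array of wild-type mouse 3. It was 3 without any 1 of the brain arrays of wild-type mice 1, 2 and 4 or of homozygous mice 1 to 4, or of the liver arrays of wild-type mouse 1 and homozygous mouse 3, and 4 without that of wild-type mouse 4.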

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

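Chosen after the results were seen were the shares between probes, the counts of signs in brain, the fits without wild-type mice 1 and 2, those with array brightness, limma on list means and the counts of other splits. Planned were Fisher's exact test near Pts, camera with an estimated correlation, the fits that left out 1 array, the authors' values, the replicate block and the fits of the differences between tissues.

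Within 10 Mb of Pts on chromosome 9, 19 liver probes and 2 brain probes passed. A sequence difference under a single probe may account for Tmem25, whose other probes moved by a median share of 0.045 in brain and -0.091 in liver of the called probe's change, taken at its lower bound. In liver it is argued against as the whole cause for Alg9 (share 0.614), Nnmt (0.907) and Trappc4 (1.06). It stays open for Mcam (0.479) and Atm (at least 0.211) in liver and for Alg9 in brain (at most 0.22). Such a difference under the Alg9 probe would act in both tissues. The share in liver cannot exclude it on top of a fall of the transcript, so as a part it stays open. Probe sequences were not matched, so whether the probes of 1 gene overlap is not known. A segment shared by all homozygous mice could give the same sign in both tissues but need not, and other effects of genotype could give it too. The sign therefore cannot settle the question. Within 10 Mb, Fxyd6 read 1.53 in liver and 0.03 in brain, and Mcam -0.99 and 0.28. Within 20 Mb 15 of 16 probes had the same sign against 40 of 61 elsewhere (Fisher's exact p = 0.0303), but probes of 1 gene are not independent. By gene it was 12 of 13 against 35 of 53 (Fisher's exact p = 0.0884), which leaves a segment open. A sequence difference under the Tmem25 probe would itself lie on such a segment, so these explanations do not exclude each other. An effect of Pts that ignores position is argued against as the cause of the gathering: in liver 14.7% of probes passed within 10 Mb against 0.736% elsewhere. An effect of the edited Pts on neighbouring genes remains open as a biological explanation and was not separated from a segment. The strain of origin and the backcrosses were not given, and no segment was genotyped.

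Lower acute phase, macrophage and glucocorticoid-responsive lists in liver. Wild-type mice 1 and 2 alone are argued against as the whole cause for macrophages. The macrophage list mean was 0.25 and 0.39 in their livers and 0.19 and 0.52 in the other wild-type livers. It lay between -0.49 and -0.06 in homozygous livers. Without those mice all 3 lists stayed lower by limma on list means. The adjusted p was 0.00604 for acute phase, 0.00974 for macrophages and 0.00688 for glucocorticoid-responsive genes. The mean went from -1.76 (SE 0.44) to -0.86 (SE 0.14), from -0.68 (SE 0.12) to -0.70 (SE 0.15) and from -1.41 (SE 0.42) to -0.53 (SE 0.10). Those mice therefore carried part of the first and the last. That fit kept only 2 wild-type livers, so it cannot settle whether those mice account for the rest. The glucocorticoid median in it was only -0.19, and camera with an estimated correlation gave 0.302 for each list. As fixed, the acute phase and glucocorticoid lists shared Lcn2. Array brightness is argued against too, since 3 of 3 lists passed with it as a covariate. A difference between genotypes stays open as a hypothesis, and the state of these mice before tissue collection was not tested.

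Lower stress and neutrophil lists in brain. Wild-type mice 1 and 2 alone may account for these lists, since 0 of 4 passed without them. Array brightness is argued against: its slope within genotypes times its difference between them gave at most 0.187 of the difference of any of the 4 lists, with 2 SE added. The 4 calls are those of camera's preset test, and 0 of 4 passed with an estimated correlation (smallest adjusted p = 0.513) or on list means. The same mice stood apart in both tissues, which a fault of single arrays would not give, and an effect of genotype on these lists in brain remains open and was not separated from those mice.

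For the liver count of 108, 1 of 35 splits, the real one, reached it and the highest other gave 1. This argues against a random grouping of the arrays but cannot exclude it, since 1 of 35 is the smallest share possible. For the 4 brain lists the splits leave chance open: 11 of the 35 splits reached 4, and the highest other gave 8. All 11 kept wild-type mice 1 and 2 on the same side, and the splits that parted these mice gave at most 1. For the 13 liver lists chance stays open too: 3 of 35 splits reached 13, and the highest other gave 14. All 3 kept the same mice together, and the splits that parted them gave at most 7. The list counts thus depend on where wild-type mice 1 and 2 fall, a structure of the mice. The splits therefore cannot separate chance from those mice. For the brain count of 2 the splits alone leave chance open, since 2 of 35 reached it. The other is the split of brighter from dimmer brain arrays, which gave 4463 and so follows a structure of the arrays; the remaining 33 gave at most 1, and with brightness as a block the count was 5. Against chance for Tmem25 stands its adjusted p of 6.93e-09 in limma, and both brain calls passed in all 8 fits that left out 1 array. The Alg9 call ended without wild-type mice 1 and 2 (adjusted p = 0.207 in limma), though its change was -1.27 (SE 0.16) there against -1.32 with all arrays. Of the 2 calls, 1 was shared with the authors' values and 1 with the replicate number as a block. For the 8 probes that differed between tissues the splits alone leave chance open too, since 2 of 35 splits of the mice reached 8; the same brightness split gave 995, the remaining 33 gave 0, and with brightness as a block the count was 15. For the liver count near Pts, 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, reached 19, and the highest other gave 0. The other splits called at most 1 liver probe anywhere, so this result follows from the total count and does not test the gathering near Pts. In brain 2 of 35 splits reached 2, the real one and the brightness split, which gave 46, while the remaining 33 gave 0. The calls near Pts were 5 with brightness as a block. Fisher's exact p of 0.000142 rests on 2 probes and does not measure variation between mice, so it cannot settle what the splits leave open.

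A sample far from the other 3 of its group was found in 9 of the 122 sets of 4 values examined, where chance gives about 1 in 20. The gap, as a share of the group's range, was 0.844 for the tetrahydrobiopterin synthesis list in homozygous liver and 0.835 for the fatty acid oxidation list in wild-type liver. It was 0.929 for Cryab in homozygous brain, where mouse 2 read 8.92 and the others 8.54 to 8.56. It was 0.895 for Phka1 in wild-type brain, where mouse 2 read 5.08 and the others 5.39 to 5.42. In homozygous liver it was 0.836 for Rgs16, where mouse 3 read 11.07 against 8.66 to 9.06, and 0.889 for Slco1a4, where mouse 2 read 7.83 against 8.29 to 8.34. In wild-type liver it was 0.889 for Sorl1, where mouse 2 read 6.03 against 4.45 to 4.63, 0.874 for Fxyd6, where mouse 2 read 5.93 against 5.31 to 5.39, and 0.947 for Fabp5, where mouse 3 read 5.85 against 6.97 to 7.03.

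The effect of genotype differed between liver and brain, by the limma test of the difference itself, by 1.78 for Mfsd2a, 1.50 for Fxyd6, -1.78 for Tubb2b, -1.67 for Syne4, -1.29 for Nos3, -1.29 for Ctps and -1.27 for Mcam. With mouse as a block the adjusted p was 0.0170 for Mfsd2a and Fxyd6, 0.0223 for Syne4, 0.0664 for Tubb2b and Mcam, 0.131 for Nos3 and 0.122 for Ctps.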

How the results depend on the processing

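Chosen after seeing the data were the fits without wild-type mice 1 and 2, array brightness as a covariate, as a block or as separate sets, limma on the list means and the lists without genes near Pts; the other alternatives were planned. Where a value below moved, the cause was not tested unless a clause gives it.

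The brain count of 2 became 1 with the authors' values, 0 with the strict detection filter, which tests fewer probes and not Tmem25 or Alg9, and 1 with the replicate number as a block. It became 5 with brightness as a block, 4 in the 4 brighter and 1 in the 4 dimmer brain arrays, and ranged from 2 to 4 with each array left out. The count of 4 brain lists became 1 without wild-type mice 1 and 2 (olfactory bulb markers), 0 with camera and an estimated correlation, 0 with fry in 1 direction, 1 with fry's mixed test (genes beside Pts) and 0 with limma on list means. Neither of those lists was among the 4. The count of brain lists ranged from 1 to 6 with each array left out. The glucocorticoid list reversed in brain without wild-type mice 1 and 2 (adjusted p = 0.292). The 2 brain probes near Pts became 1 within 5 Mb, 1 without wild-type mice 1 and 2, and 5 with brightness as a block.

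The liver count of 108 became 169 with median centring, 35 with no detection filter, which tests more probes, 27 with the strict filter, 50 with normalization over all arrays, 2931 with array weights, 32 with the replicate number as a block and 900 with all arrays in 1 fit. It became 23 without wild-type mice 1 and 2, 262 with brightness as a covariate and 599 at an adjusted p under 0.10. It ranged from 9 to 944 with each array left out. Without genes within 20 Mb of Pts the 13 liver lists became 12 of 26 tested, since tetrahydrobiopterin synthesis ended (adjusted p = 0.12). They became 0 with an estimated correlation and 5 with limma on list means. The 19 liver probes near Pts became 11 within 5 Mb and 8 without wild-type mice 1 and 2.

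The liver value of Pts passed at 0.57 with no background subtraction, 0.43 with the authors' values, 0.58 with trend and robust variance, 0.64 with array weights and 0.58 with all arrays in 1 fit. It ranged from 0.49 to 0.65 with each array left out. The count for the difference between tissues, 8, became 17 with the authors' values, 1251 with array weights, 3 with mouse as a block, 1 without wild-type mice 1 and 2 and 15 with brightness as a block. It ranged from 3 to 179 with each array left out.

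Under array weights, brain values reversed for Tph2 (-0.017), Nos1 (0.050), Apoa1 (-0.028) and Cd74 (0.071). With each array left out, the range crossed 0 in brain for Apoa1 (-0.050 to 0.17), Apoa2 (-0.18 to 0.099), Cd3e (-0.098 to 0.36) and Cd74 (-0.16 to 0.051), and in liver for Cyp17a1 (-0.51 to 0.11). Over all 154 named probe results, 2825 alternatives gave 2326 on the same side of the threshold with the same sign, 386 no longer past, 99 newly past and 14 reversed; for 17 list results, 351 alternatives gave 282, 68, 0 and 1. A block for slides could not be fitted, since slide positions were not used here. Signal over background limits probes with few detected arrays, so a change to undetected signal is a lower bound.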

Other observations

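Clock genes in liver moved in both directions, which a test of a shared direction does not read. Levels of these genes depend on the time of day, and the time of tissue collection was not given. The list had a median of 0.41 (14 tested, camera adjusted p = 0.192; 0 passed over all probes, limma), but adjusted over the list alone 7 rose and 3 fell, and fry's mixed test, which 19 of 27 liver lists passed, gave an adjusted p of 0.0174. Arntl and Nfil3 are named by the fixed rule, and the other members below were chosen after their values were seen. Lower members were the activators Arntl at -1.28 (SE 0.29) and Clock at -0.49 (SE 0.12) and the repressor Nfil3 at -1.50 (SE 0.33). Higher members were the output regulator Dbp at 2.50 (SE 0.72), the nuclear receptors Nr1d1 at 1.21 (SE 0.36) and Nr1d2 at 0.58 (SE 0.13), Tef at 1.00 (SE 0.27), Per3 at 0.99 (SE 0.38), Usp2 at 0.92 (SE 0.30) and Cry2 at 0.64 (SE 0.22). The list mean was -0.44 and -0.34 in wild-type mice 1 and 2, 0.13 and -0.06 in wild-type mice 3 and 4, and between -0.04 and 0.36 in homozygous mice. Without wild-type mice 1 and 2, Dbp read 0.97, Nr1d1 0.50, Arntl -1.06 and Nfil3 -0.84, and none of these 4 passed over all probes. The same list in brain had a median of 0.01.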
